A study of Homo sapiens with 2 samples.

How the data were processed

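RKO cells were transfected with a control siRNA or with siCHERP and collected after 72 h, and RNA was extracted with Trizol and sequenced on an Illumina HiSeq 2000, per the labels. The labels gave 2 samples, 1 per group, each with its group in its title. The deposited table held FPKM (fragments scaled by gene length and by the number mapped), computed by the authors for 51136 rows, 1 row per gene symbol, with a type for each row. Reads were aligned with Bowtie 0.12.2 and the build was hg19, per the submitters' processing notes. The counter, the gene annotation, the filters and whether poly(A) RNA was selected are not given in the sources used here. The column names were matched to the sample titles, the control column being taken as the control siRNA sample.

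Depth was worked out from the FPKM values. In rows of microRNA genes the lowest values were whole multiples of the value of 1 read, which gave 25540332 reads for the control library and 29424438 for the siCHERP library; 99.0% of these rows were whole in each library at a tolerance of 0.001. For every row, the shortest gene length at which both libraries gave whole reads within 1e-06 was then taken, which gives the smallest number of reads that fits the values. Such lengths were found for 99.9% of rows above 0, and the reads so found were 91.0% and 91.2% of the totals. They are lower bounds, so the exact (Clopper-Pearson) 95% intervals of the ratios of depth-scaled reads are at least as wide as counting error requires, and cover counting error only. Rows above 0 numbered 21774 in the control and 22858 in the siCHERP library, and rows at 1 FPKM or more 11841 and 11787. Mitochondrial rows held at least 9.56% and 10.8% of the reads.

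The difference of a gene was log2((siCHERP FPKM + 1)/(control FPKM + 1)). Genes were the rows outside the short RNA symbols with a mean of at least 1 FPKM over both libraries, and genes with a log2 difference of at least 1 either way were counted. With 1 library per group no test was run. Gene lists, fixed before the data were examined, were described by the median log2 of their members at 1 FPKM or more, by an interval of that median from the order of the members, and, for the 31 of 35 lists with at least 5 such members, by the percentile of the median among 10000 random lists of the same size matched on mean FPKM in 20 bins. A list was called where that percentile was above 97.5 or below 2.5. The named genes were also fixed by rule before the data were examined: CHERP, U2SURP, RBM17 and UPF3A; the 15 largest differences in each direction among named genes with a mean of at least 5 FPKM; up to 4 members of each list with the largest difference; and the 3 largest differences in each direction among long noncoding symbols. Genes named outside that rule are said to have been singled out after their values were seen. The RefSeq gene table of GRCh38.p14 was used for symbols and for which genes contain which snoRNAs, with no coordinates carried over; 91.3% of rows at a mean of 1 FPKM or more matched its symbols.

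Alternatives were pseudocounts of 0.1 and 0.01, a mean of 5 FPKM or no filter, 3 rescalings (to the median gene, to the upper quartile, and to the sum without the 50 most abundant rows), thresholds of 1.5-fold and 4-fold, random lists drawn from all genes, and the mean in place of the median. Restriction to mRNA rows and the use of recovered reads with no pseudocount (at least 20 reads) were added after the data were seen. The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. They were tested on simulated data for this comparison with counting error alone over 11448 genes. Of 50 genes changed in each way, 100% of those raised 4-fold and 84% of those lowered 4-fold were called at 2-fold, but 10% of those raised 2-fold and 18% of those lowered 2-fold, since a true 2-fold change lies at or under the threshold once 1 FPKM is added. None of 11248 unchanged genes was called. Of 1000 genes, the exact reads were recovered for 85.3%, and the right ratio with no more reads than the true number for 100%. Of 40 random lists 2 lay outside percentiles 2.5 to 97.5, and all 40 lists shifted by 0.5 lay above 97.5.

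XIST and genes of the Y chromosome, 411 rows, were left out throughout. Splice forms were not analysed, since the table has gene rows. Rows with short RNA symbols were kept out of the gene counts, because FPKM of rows shorter than a fragment is unstable, and are described by class. The tRNA rows, RMRP, RPPH1 and TERC are not among those symbols and stayed in the gene counts. A few genes that the rule names are not reported here.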

Results

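RNA of RKO cells, a human colon carcinoma line, was sequenced 72 h after transfection with a control siRNA or with siCHERP, an siRNA against CHERP. CHERP is a nuclear protein that associates with the U2 snRNP, the spliceosome particle that binds the intron branch site. There was 1 library per group and so no replicates, so no difference below has a replicate check and no p-value is given. Read totals, worked out from the steps between the lowest values, were 25540332 in the control library and 29424438 in the siCHERP library. Values are FPKM as deposited. Where a ratio is followed by an interval, that is its 95% exact interval. It covers counting error only, because PCR reads without molecular identifiers are not independent molecules.

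CHERP itself was measured first, as a check of the labels. It stood at 26.4 FPKM in the control library and 22.1 FPKM in the siCHERP library, a ratio of 0.837 (0.793 to 0.883) from at least 2760 and 2662 reads. The direction was that of the label, but the log2 difference of −0.25 lay at percentile 36.8 among the 3425 genes within 2-fold of its mean level. After rescaling to the median gene or to the upper quartile the ratio was 0.906 or 0.931. CHERP mRNA therefore did not stand apart from other genes of like abundance in this pair of libraries, and every direction below rests on the labels of the libraries, which CHERP does not settle; with the labels exchanged, higher and lower would trade places. Of its partners in the U2-associated complex, U2SURP went from 66.7 to 58.3 FPKM (ratio 0.874, 0.853 to 0.896) and RBM17 from 104 to 107 FPKM (ratio 1.03, 0.999 to 1.05). UPF3A, a factor of nonsense-mediated decay whose splicing has been linked to CHERP, went from 48.1 to 54.1 FPKM (ratio 1.12, 1.07 to 1.18). The median log2 of these 3 genes was 0.04, and none differed by 2-fold. The deposited table has 1 value per gene, so splice forms of UPF3A were not analysed here.

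The comparison of the library labelled siCHERP with the control library asks which transcripts differ between cells given the siRNA against CHERP and cells given the control siRNA. Genes at least 2-fold higher in the siCHERP library included CXCL8, BIRC3 and NFKBIA of the NF-κB response list, BBC3, GDF15 and MDM2 of the p53 target list, and GADD45A, PPP1R15A and DDIT3. Mitotic genes such as ASPM, DLGAP5 and TOP2A, and hypoxia-responsive genes such as BNIP3L and ENO2, were at least 2-fold lower as deposited; TOP2A was not after rescaling to the median gene (−0.98) or to the upper quartile (−0.95). Most of the transcriptome differed little, with 97.2% of the 11448 genes at a mean of 1 FPKM or more within 2-fold. On the log2 scale of FPKM + 1, which understates the differences of low genes, 141 genes were at least 2-fold higher and 176 at least 2-fold lower. Ratios given below are of FPKM as deposited, so a gene of low level can have a ratio above 2 or below 0.5 and still not be counted as past 2-fold. The median log2 of all these genes was −0.12, and 5% of genes lay below −0.79 and 5% above 0.59. Higher genes made up 44.5% of the 2-fold differences as deposited, 65.7% (190 higher, 99 lower) after rescaling to the median gene and 71.7% (210 higher, 83 lower) after rescaling to the upper quartile. Rescaling to the sum without the 50 most abundant rows left it at 42.9% (138 higher, 184 lower). The balance of higher and lower genes thus differed between scalings, so the medians of gene groups are to be read against the all-gene median of −0.12.

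**Figure D1:**
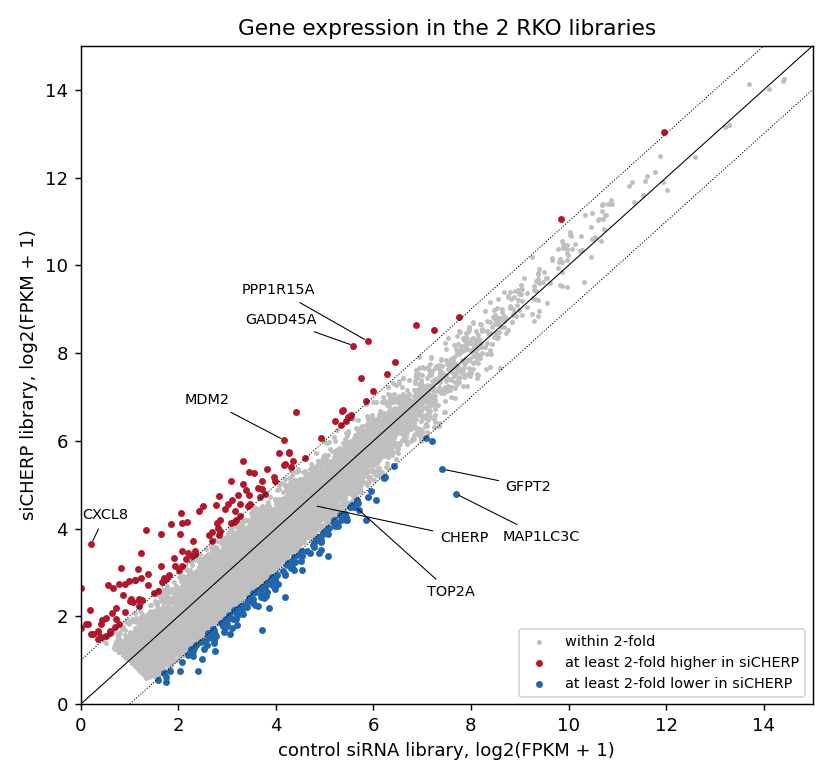
Each point is 1 of the 11448 genes with a mean of 1 FPKM or more, with log2(FPKM + 1) in the control siRNA library on the x axis and in the siCHERP library on the y axis; dotted lines mark 2-fold. The 141 genes at least 2-fold higher (red) and the 176 at least 2-fold lower (blue) lie outside the band that holds 97.2% of genes, and CHERP (26.4 and 22.1 FPKM) lies inside it.

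The 15 largest positive differences among genes at 5 FPKM or more began with CXCL8, which encodes a neutrophil-attracting chemokine. CXCL8 went from 0.161 to 11.5 FPKM, a ratio of 71.5 with a wide interval (34.5 to 179) because the control value rested on at least 7 reads. GADD45A, a gene induced by DNA damage and growth arrest, went from 47.2 to 287 FPKM (ratio 6.08, 5.49 to 6.76). PPP1R15A, whose product directs a phosphatase to eIF2α, went from 58.0 to 308 FPKM (5.32, 5.13 to 5.51), and DDIT3, which encodes the transcription factor CHOP, from 9.07 to 45.6 FPKM (5.02, 4.41 to 5.73). BIRC3, an inhibitor of apoptosis, stood at 2.61 and 16.1 FPKM, and NFKBIA, which encodes the NF-κB inhibitor IκBα, at 20.4 and 99.8 FPKM. BBC3, the pro-apoptotic PUMA gene, went from 4.67 to 22.0 FPKM, and GDF15, a secreted stress-response factor, from 3.56 to 16.7 FPKM. The kinase gene SIK1 had a ratio of 7.26, the aldehyde oxidase gene AOX1 6.12, the zinc finger gene ZNF79 5.17, KBTBD8 4.62 and the pyruvate dehydrogenase phosphatase gene PDP1 4.38. The unnamed loci LOC105375039 and LOC105379283 had ratios of 9.67 and 6.47.

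The largest negative difference was that of MAP1LC3C, a member of the LC3 family of autophagy proteins, which stood at 205 FPKM in the control library and 26.8 FPKM in the siCHERP library (ratio 0.130, 0.122 to 0.140). GFPT2, an enzyme of the hexosamine pathway, stood at 170 FPKM in the control library and had a ratio of 0.235 (0.227 to 0.244), and METTL7B went from 12.2 to 2.21 FPKM (0.182, 0.131 to 0.248). BNIP3L, a mitophagy receptor, went from 13.5 to 3.55 FPKM, the lipid transporter ABCA2 from 17.3 to 4.41 FPKM, and the phosphatidate phosphatase LPIN1 from 65.1 to 24.0 FPKM. RAB3IP, an exchange factor for a Rab GTPase, had a ratio of 0.291, the long noncoding RNA LUCAT1 0.309 and the spindle gene ASPM 0.330. The other 6 of the 15 were EHBP1L1, LOC105370578, CNTNAP1, the proteoglycan gene AGRN, SFXN3 and the protease inhibitor gene SERPINB1, with ratios from 0.307 for CNTNAP1 to 0.354 for LOC105370578.

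The p53 target genes were higher as a group. Of 28 measured members, 11 were at least 2-fold higher in the siCHERP library and none 2-fold lower, and 27 lay above the all-gene median. The list median log2 was 0.75 (95% interval over members 0.43 to 1.15), at percentile 100 among 10000 random lists matched on abundance. MDM2, which encodes a ubiquitin ligase, went from 17.0 to 63.8 FPKM (ratio 3.74, 3.60 to 3.89), and SESN2, a stress-induced inhibitor of mTORC1 signalling, from 6.74 to 20.7 FPKM (3.07, 2.80 to 3.36). CDKN1A, the p21 cell cycle inhibitor, went from 44.5 to 93.0 FPKM (2.09); it was singled out after its values were seen. Apoptosis regulators had 2 of 23 members at least 2-fold higher, BBC3 and the anti-apoptotic BCL2L1 (40.4 to 103 FPKM), while PMAIP1 (ratio 1.96) did not reach 2-fold. The median of that list was 0.08, at percentile 96.8.

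Genes of the NF-κB response were also higher, with 5 of 14 measured members at least 2-fold higher and none 2-fold lower. Their median log2 was 0.66 with a wide interval (0.138 to 2.235), at percentile 100, and the lowest member was at −0.73. Besides CXCL8, BIRC3 and NFKBIA, the signalling adaptor TRAF1 went from 0.827 to 4.64 FPKM. Among immediate early genes, 4 of 25 were at least 2-fold higher and none 2-fold lower, with a median log2 of 0.37 (−0.07 to 0.79) and percentile 100. They were ATF3 (0.771 to 7.63 FPKM, ratio 9.90, 7.34 to 13.6), the signalling inhibitor SPRY2 (5.82 to 22.2 FPKM), MYC (150 to 369 FPKM, 2.47, 2.38 to 2.55) and FOSL1 (214 to 449 FPKM). ATF4 and amino acid response genes had 4 of 16 members at least 2-fold higher, namely ATF3, SESN2 and the cystine and amino acid transporter genes SLC7A11 (0.645 to 2.84 FPKM) and SLC3A2 (39.4 to 81.6 FPKM). The median of that list was 0.11, at percentile 96.9, inside the range from percentile 2.5 to 97.5. NRF2 targets had 2 of 14 members at least 2-fold higher, the heme-degrading enzyme HMOX1 (8.35 to 26.1 FPKM) and SLC7A11, with OSGIN1 (ratio 2.45) and the ferritin gene FTL (1.92) next. Their median was 0.27 (−0.30 to 0.97), at percentile 99.4. With a mean of 5 FPKM or more it was 0.16, and with no filter 0.09. In the unfolded protein response list, PPP1R15A and DDIT3 were at least 2-fold higher among 20 members, DNAJB9 and ERN1 had ratios of 1.76 and 1.91, and the list median of −0.04 (percentile 58.0) differed in sign from the mean of 0.28. Type I interferon response genes had no member of 21 past 2-fold and a median of −0.30 (percentile 9.62); ISG20 (0.344), IFI35 (0.525), OAS2 (0.525) and OAS3 (0.573) had the largest differences.

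Cell cycle genes were lower as groups. The G2/M list, which holds genes of mitosis, had 7 of 54 members at least 2-fold lower and none 2-fold higher, and 3 members lay above the all-gene median. Its median log2 was −0.72 (−0.80 to −0.65), at percentile 0. DLGAP5 went from 29.5 to 12.4 FPKM (ratio 0.421, 0.371 to 0.477), the kinetochore gene NUF2 from 58.2 to 25.3 FPKM (0.434), the topoisomerase gene TOP2A from 47.9 to 21.9 FPKM (0.457) and the mitotic kinesin gene KIF23 from 47.3 to 21.7 FPKM (0.458). The G1/S list had 1 of 43 members at least 2-fold lower, the replication factor CDC45 (36.6 to 16.6 FPKM, 0.453, 0.420 to 0.488), and a median of −0.46 (−0.58 to −0.37) at percentile 0. After rescaling to the median gene or to the upper quartile, 2 of 54 G2/M members and 0 of 43 G1/S members were at least 2-fold lower; CDC45, TOP2A and KIF23 were then between −0.99 for CDC45 and −0.94 for KIF23 on the log2 scale. DSCC1 (0.491), E2F8 (0.448) and EXO1 (0.544) followed it. Homologous recombination and Fanconi genes had no member of 27 past 2-fold, but a median of −0.47 at percentile 0.05, with FANCI at a ratio of 0.529, BRCA1 at 0.521, BRCA2 at 0.479 and FANCC at 0.501 (0.247 to 0.981). Replication-dependent histone genes went the other way. None of 13 passed 2-fold, the median was 0.32 (−0.04 to 0.79) at percentile 99.9, and HIST1H2BD (2.03), HIST3H2A (1.88), HIST1H2BK (1.74) and HIST1H4C (1.64, 0.691 to 4.17) had the largest differences. The histone median depended on the filter, at 0.79 with a mean of 5 FPKM or more and 0.24 with no filter. Histone mRNAs mostly lack a poly(A) tail, and short RNAs without such a tail were also higher in the siCHERP library. Whether the transcripts counted for these members lacked a tail cannot be told from gene rows, so a link between the 2 was not tested.

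**Figure D2:**
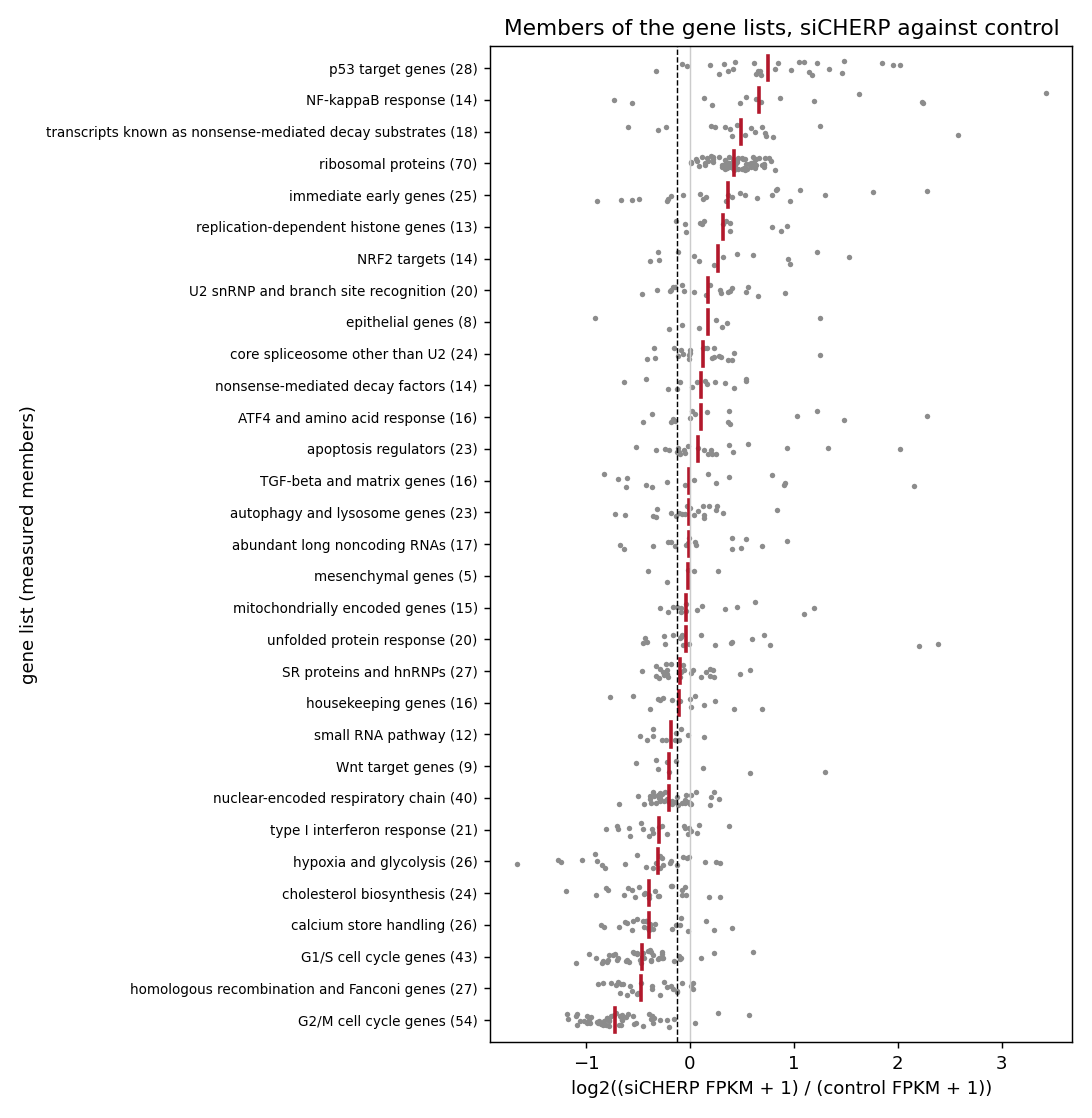
Each grey point is a measured member of a gene list, with its log2((siCHERP FPKM + 1)/(control FPKM + 1)) on the x axis; red bars mark list medians, numbers in parentheses the members measured, and the dashed line the all-gene median of −0.12. Among the 31 fixed lists with at least 5 measured members, which are those drawn, the p53 target list had the highest median (0.75) and the G2/M list the lowest (−0.72).

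Ribosomal protein genes differed in the same direction relative to other genes. All 70 lay above the all-gene median and none passed 2-fold, with a median log2 of 0.42 (0.37 to 0.46) at percentile 100, and members ranged from 0.01 for RPS7 to 0.82 for RPS12. Among the largest ratios were those of RPS12 (1.76), RPL28 (1.72) and RPL13A (1.65). These genes have processed pseudogenes that can share reads with them. Known substrates of nonsense-mediated decay, the pathway that UPF3A modulates, had 2 of 18 members at least 2-fold higher, none 2-fold lower, and a median log2 of 0.49 at percentile 100. The members past 2-fold were GADD45A and ATF4 (76.8 to 184 FPKM, ratio 2.40, 2.31 to 2.48), which are also stress-response genes, followed by GADD45B (1.81) and the snoRNA host gene SNHG5 (1.67). SNHG rows can hold reads from the snoRNAs inside them, and snoRNAs were higher as a class in the siCHERP library. Not every snoRNA rose more than its host. SNORD50B, inside SNHG5, had a log2 of 0.31 against 0.74 for SNHG5. The snoRNAs inside GAS5 and SNHG1 lay on both sides of their hosts. Nonsense-mediated decay factors had no member of 14 past 2-fold and a median of 0.11 (percentile 95.8), with SMG5 at 0.629, SMG6 at 0.716, UPF3B at 1.46 and RBM8A at 1.46.

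As deposited, components of the splicing machinery other than PRPF3 differed by less than 2-fold. None of 20 members of the U2 snRNP and branch site list passed 2-fold, and the median of 0.18 lay at percentile 96.4. The largest ratios were those of SF3A2 (32.0 to 61.1 FPKM, 1.91, 1.79 to 2.04), which passed 2-fold after rescaling to the median gene (log2 1.02) or to the upper quartile (1.06), PUF60 (1.58), SF3A1 (1.49) and PHF5A (1.47). In the list of other core spliceosome genes, PRPF3 went from 35.9 to 86.8 FPKM (2.42, 2.20 to 2.67), while PRPF4 (1.33), SNRPD2 (1.34) and SNRPG (0.746) were among the other 23, and the median was 0.13 (percentile 95.4). Against random lists drawn without matching on abundance, these lists lay at percentiles 99.6 and 99.3. SR proteins and hnRNPs had no member of 27 past 2-fold and a median of −0.10 (percentile 11.4), with HNRNPA1 at 1.49, CLK3 at 1.53, HNRNPA2B1 at 0.727 and SRSF7 at 0.795.

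Several lists of metabolic and calcium genes were lower. Hypoxia and glycolysis genes had 4 of 26 members at least 2-fold lower and none 2-fold higher, with a median log2 of −0.31 at percentile 0.24. They were BNIP3L, the glycolytic regulator PFKFB4 (3.10 to 0.700 FPKM), ENO2 (42.3 to 17.2 FPKM) and PDK1, which inhibits pyruvate dehydrogenase (8.23 to 3.48 FPKM). After either of those rescalings PDK1 was within 2-fold (−0.95 and −0.92) and 3 of 26 were lower. Cholesterol biosynthesis genes had 1 of 24 at least 2-fold lower, the sterol carrier gene STARD4 (8.49 to 3.15 FPKM, ratio 0.371), and a median of −0.39 at percentile 0.23, with TM7SF2 at 0.429, DHCR7 at 0.520 and LSS at 0.541. The list of calcium store handling, a process in which CHERP was first described, also holds genes of wider calcium signalling. It had no member of 26 past 2-fold and a median of −0.40 (−0.51 to −0.17) at percentile 0.16, which does not single out the stores. PPP3CA had a ratio of 0.459, ATP2B1 0.510, CALM2 0.621 and the IP3 receptor gene ITPR3 0.643. Nuclear-encoded respiratory chain genes had a median of −0.21 at percentile 2.27, or 15.1 without matching on abundance, with none of 40 past 2-fold and UQCRC1 (0.619), NDUFV1 (0.702), NDUFV2 (0.735) and NDUFS7 (0.748) lowest. Mitochondrially encoded genes were not lower as a group. They had a median of −0.04 and a mean of 0.19, at percentile 8.50, or 75.1 without matching on abundance, and 12 of 15 lay above the all-gene median. The 2 of 15 that were at least 2-fold higher were the ribosomal RNAs RNR1 (2.28) and RNR2 (2.14), ahead of ND1 (1.54) and COX1 (1.37).

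The remaining lists lay between percentiles 2.5 and 97.5. Wnt targets had MYC as the 1 of 9 members past 2-fold, a median of −0.20 and a mean of 0.03 (percentile 27.0), with CD44 at 1.51, TCF7 at 0.615 and NKD1 at 0.651. TGF-β and matrix genes had 1 of 16 at least 2-fold higher, the collagenase gene MMP1 (0.476 to 5.57 FPKM), a median of −0.01 and a mean of 0.11 (percentile 73.5), with CYR61 at 1.91, CTGF at 2.78 and LAMB1 at 0.551. Among 8 measured epithelial genes KRT8 was at least 2-fold higher (3.57 to 9.91 FPKM), CA2 (0.471), EPCAM (1.31) and KRT18 (1.24) were not counted as past 2-fold, and the median was 0.17 (percentile 95.9). The 5 measured mesenchymal genes had a median of −0.02 (percentile 66.0), with VIM at 0.693, AXL at 1.21, ITGA5 at 0.850 and SNAI1 at 1.05. Autophagy and lysosome genes had a median of −0.01 over 23 members (percentile 84.4; SQSTM1 1.80, GLA 0.586, ULK1 0.547, ATP6V1H 0.774). Small RNA pathway genes had a median of −0.19 over 12 members (percentile 43.1), with AGO2 (0.705), DICER1 (0.737), DROSHA (0.765) and DGCR8 (0.771) lowest. Housekeeping genes had a median of −0.10 over 16 members (percentile 11.8), with TUBA1B at 0.684, RPLP0 at 1.34 and EEF1A1 at 1.61. Abundant long noncoding RNAs had a median of −0.01 over 17 members (percentile 76.6), with SNHG7 at 1.69, OIP5-AS1 at 0.613 and H19 at 0.375 (0.207 to 0.655). Rescaling to the median gene turned the sign of 8 of the list medians near 0, those of the SR protein, unfolded protein response, TGF-β, mesenchymal, mitochondrially encoded, autophagy, housekeeping and abundant noncoding lists. The same rescalings also took PMAIP1, HIST1H2BD, OSGIN1, FTL, CYR61 and SNHG16 past 2-fold, and the upper quartile alone HIST3H2A and CTGF. Markers of other cell types were scarce. Of the fibroblast markers, ACTA2 alone of 12 was measured (1.16 to 6.11 FPKM), of the leukocyte markers CD68 alone of 16 (210 to 259 FPKM), and of the endothelial markers none of 10.

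Of the 31 fixed lists with at least 5 measured members, 7 lay above percentile 97.5 and 7 below percentile 2.5, where 1.55 would by chance if lists were independent. The lists share members and genes within a list vary together, so the percentiles describe these 2 libraries and do not test the treatment.

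Noncoding RNA differed by class. Of the 1026 rows that the table types as ncRNA, 43 were at least 2-fold higher and 16 at least 2-fold lower, and without short RNA symbols 32 of 999 were higher and 15 lower; LOC105379283 was among the higher and LUCAT1 among the lower. The symbol patterns for long noncoding RNA (LINC, SNHG, microRNA host genes and antisense names) take in only part of these rows and neither of those genes. Of 191 rows with such symbols, none was at least 2-fold higher and 3 were at least 2-fold lower, with a median log2 of −0.06. Those 3 were LINC01358 (32.4 to 13.6 FPKM), PRKAG2-AS1 (3.91 to 1.33 FPKM) and MNX1-AS1 (7.26 to 2.93 FPKM). After rescaling to the upper quartile PRKAG2-AS1 (−0.98) and MNX1-AS1 (−0.96) were within 2-fold, and MNX1-AS1 also after rescaling to the median gene (−0.99). SNHG16 (17.3 to 34.1 FPKM), FBXL19-AS1 (0.981 to 2.53 FPKM) and THUMPD3-AS1 (3.26 to 6.58 FPKM) had the largest positive differences among these 191. Whether counting used the strand is not given in the sources used here, so reads of antisense RNAs and of the genes they overlap cannot be separated. Among short RNA symbols, 199 of 418 were at least 2-fold higher and 9 at least 2-fold lower, with a median log2 of 0.95. Small nucleolar RNAs, which guide the modification of ribosomal RNA, had 135 of 205 at least 2-fold higher and none 2-fold lower (median 1.37, 1.20 to 1.62). Their share of all reads was at least 0.019% in the control library and at least 0.0593% in the siCHERP library. By symbol, which does not sort every row as the type column of the table does, 81 of 131 box C/D and 55 of 74 box H/ACA snoRNAs were at least 2-fold higher. Transfer RNA rows, which are not among the short RNA symbols and so were within the gene counts, had 7 of 33 at least 2-fold higher and 1 lower.

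**Figure D3:**
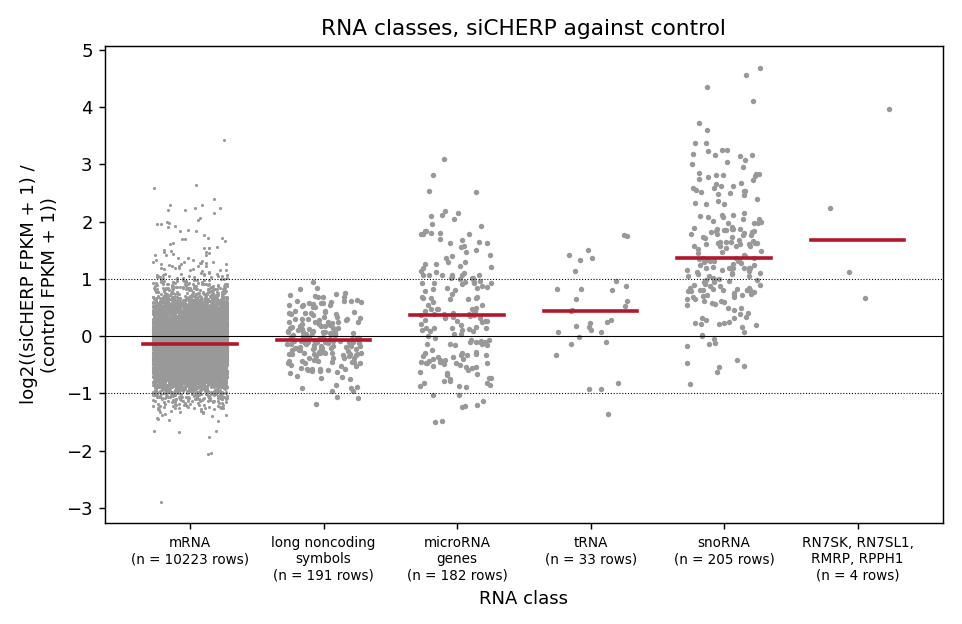
Each point is 1 row of the table, grouped on the x axis by RNA class, with log2((siCHERP FPKM + 1)/(control FPKM + 1)) on the y axis; red bars mark class medians and dotted lines 2-fold. The snoRNA median was 1.37 and the mRNA median −0.14; RN7SK, RN7SL1, RMRP and RPPH1 are shown together and were chosen after their values were seen.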

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

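The tests on tRNA rows, on snoRNA host genes, on scaling and on CHERP (counting error, genes of like abundance, swapped labels) were chosen only after the results were seen; those on intron reads and on trends with gene length and abundance were written before.

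Rows with short RNA symbols, which stayed outside the gene counts, held signal above the control library. RN7SK, the noncoding RNA that restrains the elongation factor P-TEFb, went from 4.60 to 86.8 FPKM (at least 39 and 848 reads, ratio 18.9, 13.7 to 26.7), and RN7SL1, the RNA of the signal recognition particle, from 3.93 to 22.2 FPKM (ratio 5.64, 3.83 to 8.59). At least 2-fold higher in siCHERP were 135 of 205 snoRNA rows and 51 of 182 microRNA gene rows, against 0 and 8 lower. The microRNA rows had a median of at least 9 reads over both libraries.

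As for the source of the snoRNA difference, host RNA levels were not higher by as much. The 88 measured hosts had a median log2 of 0.28 (0.22 to 0.38) against 1.37 for the snoRNAs. Of 176 snoRNAs, 86.4% lay above their host. Host rows give RNA levels and not transcription or intron output, so higher output of the host genes was not settled. Another 18 snoRNAs were matched to no host gene and had a median of 1.27. The matching went by symbol, so a host under another symbol could be missed. More intron reads in general were not settled. Noncoding rows inside coding genes exceeded those outside any gene by 0.13 (0.01 to 0.23), the direction which that explanation predicts. The interval lay below the size set beforehand for it and below the snoRNA median of 1.37. However, those rows are annotated transcripts and do not measure intron reads, so the comparison cannot decide. A larger share of non-polyadenylated RNA in the siCHERP library may be part of it but was not settled: the 33 tRNA rows had a median log2 of only 0.44 (0.11 to 0.83), above the all-gene median and below the snoRNA interval. RN7SK, RN7SL1, RMRP and RPPH1, picked after their values were seen, had a median of 1.68. The interval of RMRP spanned 1 (0.914 to 4.70, from at least 10 and 23 reads). TERC, the telomerase RNA, was at 1.13 FPKM in both libraries. It rested on at least 13 and 15 reads, and the interval of its ratio (0.445 to 2.29) does not exclude a 2-fold difference. With 1 library per group, a difference in library preparation and an effect of siCHERP on these RNAs both stay open.

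The higher p53 targets were weighed next. A trend with gene length and abundance is argued against, since the list median was 0.94 (0.58 to 1.44) after both trends were removed, against 0.75 before. Removing the trends also takes out the all-gene median of −0.12, and measured from that median the list stood at 0.88 before. Scaling, which moves all genes alike, is argued against, since the list median lay 0.88 (0.55 to 1.27) above that of all genes. A response of the cells to siCHERP may underlie it, but differences in culture or transfection between the 2 dishes were not tested and stay open.

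The small difference of CHERP was weighed last. Counting error alone is argued against, since the interval of the ratio ended at 0.883, below 1. A difference of the size that most genes show stays open, since CHERP lay at percentile 36.8 of genes of like abundance. Swapped labels cannot be told apart from a weak or recovered knockdown, since a CHERP ratio of 0.837 has the direction of the label but not a size that would settle it. Protein levels were not analysed here.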

How the results depend on the processing

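The restriction to mRNA rows and the recovered reads without a pseudocount were chosen only after the results were seen. None of 1146 alternative values reversed a called result. Only values of called lists, of genes past 2-fold and of CHERP could count as reversed, so the total overstates what was tried. The medians of 8 lists that were not called changed sign under a rescaling. Against 141 genes higher and 176 lower, a pseudocount of 0.1 gave 219 and 479 and of 0.01 gave 234 and 531, because low genes are damped less. Recovered reads without a pseudocount, among 11400 genes with at least 20 reads, gave 230 and 532. The 10223 mRNA rows alone gave 97 higher and 156 lower, so the other rows made up more of the higher than of the lower genes. A mean of 5 FPKM left 92 higher among fewer genes. Rescaling to the median gene left 99 lower and to the upper quartile 83, thresholds of 1.5-fold gave 573 higher and 1445 lower, and of 4-fold 15 and 3. Under rescaling to the median gene and to the upper quartile, the median log2 was −0.35 and −0.32 for G1/S genes, −0.61 and −0.57 for G2/M genes and 0.53 and 0.57 for ribosomal proteins, and the CHERP log2 was −0.14 and −0.099, since 1 factor shifts all genes. The U2 snRNP list lay at percentile 99.57 against random lists from all genes, for which the cause was not tested; the other core spliceosome list (99.26) and the apoptosis list (97.51) did so too, and the respiratory chain list moved inside the range (15.06). Of 248 list medians, 12 left their interval, and of 840 values for single genes, 265 left their counting interval. No paired analysis was possible because there was 1 library per group. Keeping the highest row per symbol was not run, since no symbol was on more than 1 row, and isoform shares were not run on gene rows. Depth limits the lowest genes, such as CXCL8 with at least 7 control reads.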

Other observations

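The heat shock and zinc finger groups and the RNAs below were chosen only after their values were seen, and no explanation was tested for them.

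Heat shock chaperones had 4 of 14 measured members at least 2-fold higher in the siCHERP library, none 2-fold lower, and a median log2 of 0.52 at percentile 99.98. HSPA1B went from 52.4 to 172 FPKM (ratio 3.29, 3.16 to 3.41) and HSPA1A from 7.14 to 22.6 FPKM (3.17, 2.85 to 3.53); these near-identical genes share reads, so how their signal divides is uncertain. HSPH1 had a ratio of 2.07 and DNAJB4 2.08 (log2 0.99 after rescaling to the sum without the 50 most abundant rows), BAG3, a co-chaperone, had a ratio of 1.64, and the constitutive chaperone HSPA8 had a ratio of 0.623. Zinc finger genes with ZNF symbols had 13 of 351 at least 2-fold higher, none 2-fold lower, and a median of 0.27 (0.23 to 0.32).

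The gene row of MIR34A went from 8.54 to 31.8 FPKM (ratio 3.73, 2.37 to 6.08, from at least 24 and 103 reads). SNORA64 had the largest log2 difference of the 205 snoRNAs, from 8.47 to 244 FPKM (ratio 28.8, 19.9 to 43.2), and SNORD14E went from 9.30 to 209 FPKM.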
